A study of Daphnia magna with 22 samples.

How the data were processed

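Each sample was whole-body total RNA of Daphnia magna, per the labels, from 30 pooled individuals that were 21 days old, kept at 22 degrees C with 16 h of light and 8 h of darkness. Of each RNA, 200 ng was labelled with Cy3, per the labels' protocols, and hybridised to 1 array of a custom Agilent design with 62976 spots. The spot intensity values were made by Agilent Feature Extraction 10.7.3.1, per the file headers, as a processed signal with background subtracted within the array and no normalization between arrays. Median spot and local background intensity, and 0/1 flags for spots well above background, saturated or outlying, stand beside it per the file headers. The deposited series table holds log2 values for 10935 ESTs. The submitters' processing notes name limma without its role. Set against the scanner values, the columns of that table follow quantile-normalized log2 median signal averaged per EST, with no background subtraction visible (lowest correlation 0.9996 over the arrays, and 0.999 for a difference between 2 arrays). Its column medians lay between 7.44 and 7.56, and its constant offset stays unknown.

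Groups came from the titles of the samples (generation, dose and replicate). The design text states duplicates, while the 1 mg/L groups of F3 and F4 have 3 samples each, all of which were used. The labels do not say whether replicates came from separate aquaria, so p-values measure the spread between these samples, part of which is technical. No pair of replicates held identical values. The SD of the log2 difference within pairs was between 1.16 and 3.07 times the noise between duplicate spots. Repeated hybridisations of 1 RNA could exceed that noise too, so the ratio does not show that replicates were separate samples. Every sample was counted once. The arrays lay on 3 slides, each scanned once. Slide 1 held F1 at 0, 0.1 and 1 mg/L, slide 2 held F1 at 10 mg/L, both F2 groups and the F3 control, and slide 3 held F3 at 1 mg/L and both F4 groups.

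Control spots (1319 per array) and spots marked as outliers were left out. The log2 processed signal was averaged over the spots of a probe (28859 of 32798 probes had 2 spots), and each array's 75th percentile was subtracted. Probes well above background on at least 2 of the 22 arrays were tested, 28876 in all. One model with a mean for each of the 10 groups was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 12 residual and 1.97 prior degrees of freedom). P-values were adjusted by Benjamini-Hochberg, two-sided, at a threshold of 0.05. Main fits, comparisons, alternatives and the rule for named items were chosen before the data were examined. A probe not well above background on any array of a group has only a bound there, and no fold is given for it. Probes of 1 EST were tested singly, and the agreement among the 3 probes of an EST (intraclass correlation of log2 differences) was between 0.747 for 0.1 mg/L against control and 0.973 for 10 against 1 mg/L.

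None of the EST names matched the gene table used here (0 of 10935), so no gene names are printed, and the 26 gene lists fixed beforehand could not be applied. In that case the rule named at most 2 probes with the largest rise and 2 with the largest fall per comparison, 1 probe per EST (highest mean signal), past the threshold, with no overlap between the groups' arrays and measured above background on at least 1 array of each group. For F-tests the brightest probes of their ESTs with the smallest p and measured in every group were named, and where fewer than 4 probes passed, those with the smallest p. Alternatives fixed then were median centring, quantile normalization, normexp background correction (offset 50) with quantile normalization, the authors' values, other filters and variance models, the replicate number as a block, a 2-fold minimum, fits on the compared groups only, controls of the same slide and leaving out each replicate or generation. Normexp used the median spot signal in place of the mean signal named in the plan. The mean over the probes of an EST, centring on the 6 of 10 E1A spike-ins above background on all arrays, leaving out 2 arrays together, crossed replicate numbers, and 1 control array for each dose were chosen after seeing the data.

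The fit was tested on simulated data with the spread of the 28876 probes, the same in all groups, and 200 probes changed. It recovered 30% of 2-fold and 76% of 4-fold changes for F1 1 mg/L against control, 45% and 82% for F1 10 mg/L, 31% and 72% for F2, 42% and 76% for F3, 73% and 98% for the mean over generations, and 9% and 54% for the interaction. False calls among the unchanged probes numbered between 2 (F2) and 13 (F4), with 12 each for F1 0.1 and 10 mg/L.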

Results

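Transcript levels were measured in whole bodies of the water flea Daphnia magna, a small freshwater crustacean, after exposure to tetracycline, an antibiotic that blocks protein synthesis on bacterial ribosomes. Animals of the F1 generation were exposed to 0, 0.1, 1 or 10 mg/L, and the control and the 1 mg/L exposure were carried on through the F2, F3 and F4 generations. Each replicate pooled 30 animals that were 21 days old, and 22 arrays of 1 colour were hybridised, 1 per replicate. Of the 10 groups, 8 had 2 replicates, and the 1 mg/L groups of F3 and F4 had 3. The array carried probes for expressed sequence tags (ESTs, single sequencing reads of cDNA clones), 3 for nearly every EST. The probes are known here by EST clone name only, so changes are described for EST clones and for sets of them, with no gene names. Of 32798 probes, 28876 from 10318 ESTs were tested. The 75th percentile of the processed signal ranged from 904.3 to 2047 between arrays, and between 72.03% and 82.98% of the probes were well above background. The number of arrays limits the precision of every comparison.

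The arrays parted first by 10 mg/L and by the F4 generation. The first principal component held 34.6% of the variance. On it the F1 10 mg/L arrays lay at 152.3 and 75.3, the F4 control arrays at 58.7 and 58.3, and the F4 1 mg/L arrays at 80.1, 169.8 and 61.5, whereas the arrays of the remaining groups lay between -78 and -18. Replicates differed most in the F4 1 mg/L group (residual SD 0.617 on the log2 scale, n = 3) and least in the F2 controls (0.277, n = 2).

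**Figure D1:**
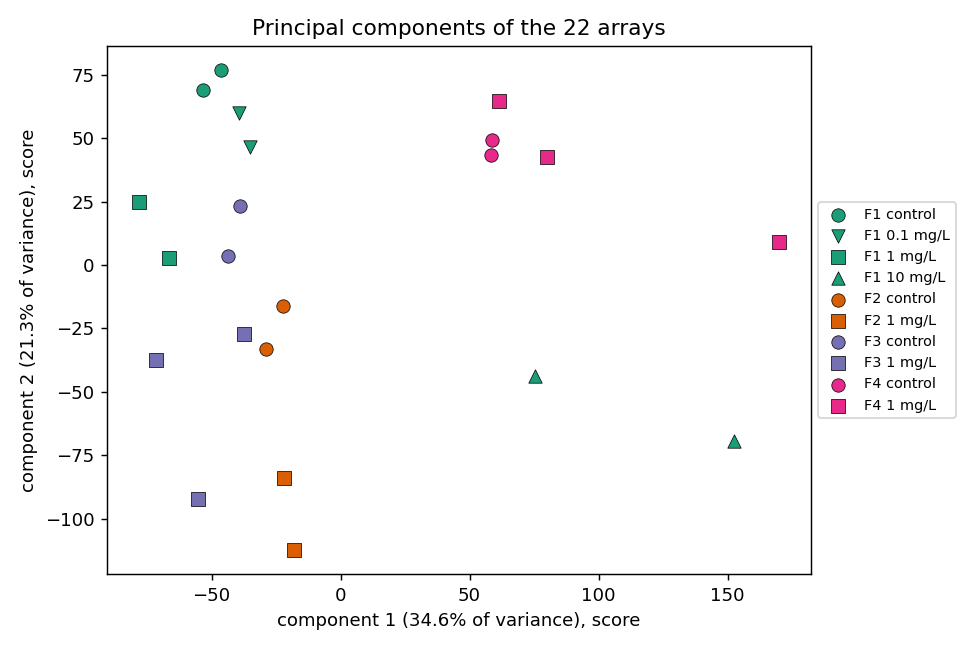
Scores of the 22 arrays on the first 2 principal components of the normalized log2 signals, 1 point per array, with colour for the generation and shape for the dose. The F1 10 mg/L arrays (152.3 and 75.3) and the 5 F4 arrays lie to the right, and all others lie below 0 on component 1.

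At 0.1 mg/L in F1, the lowest dose, few probes passed the test against the control. The probe of IGU001_0036_A10.r fell by 0.87 on the log2 scale (SE 0.13, adjusted p = 0.039 by limma), from -2.29 ± 0.08 (SD, n = 2) to -3.17 ± 0.07 (n = 2), and it was lower on both exposed arrays than on both controls. The change passed for 1 of the 3 probes of this EST. In all, limma called 7 probes, 2 higher and 5 lower, each from a different EST. At an unadjusted p under 0.05 there were 1565 probes, where chance gives 1444. The count was 0 without replicate 1 (631 at an unadjusted p under 0.05) and 1 without replicate 2 of the exposed group, and 83 or 63 without control replicate 1 or 2.

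At 1 mg/L in F1, the dose later carried through 4 generations, 2 ESTs that were dim in the controls rose most among the probes measured in both groups. IGU001_0004_B08.f went from -5.47 ± 0.43 (SD, n = 2) to -1.45 ± 0.75 (n = 2), a log2 difference of 4.02 (SE 0.79, adjusted p = 0.0296). At 0.1 mg/L it already lay at -1.33 ± 0.05 (n = 2), a difference from the controls that did not pass the test. IGU001_0029_H09.f, well above background on 1 of 2 control arrays, rose by 3.93 (SE 0.59, adjusted p = 0.00754), to -2.22. Controls of the later generations, on other slides, lay above the F1 controls for both ESTs. In F2, F3 and F4 controls IGU001_0004_B08.f lay at 0.25, -3.32 and -1.47, and IGU001_0029_H09.f at -0.98, -3.47 and -2.94. Among the falls, WTH001_0011_L05.f had a log2 difference of -3.02 (SE 0.33, adjusted p = 0.00148) and IGU001_0028_H08.f one of -2.95 (SE 0.34, adjusted p = 0.00241). All 3 probes of each of these ESTs were called in the same direction. In all, limma called 303 probes, of which 196 were lower. Of the ESTs, 25 had at least 2 probes called higher and 62 at least 2 called lower. The share of higher calls was 35.3%, against 22.4% with median centring, 22.5% with quantile normalization, 17.5% after normexp, 17.6% with the authors' values, 17.3% with spike-in centring and 50.1% with array quality weights. Without 1 array the count was 81 or 141 (control replicate 1 or 2) and 148 or 41 (exposed replicate 1 or 2).

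At 10 mg/L in F1, about 35.17% of the probes changed. A set of 833 probes from 297 ESTs fell at least 8-fold, with a median fitted log2 difference of -5.17 (quartiles -6.44 and -3.92). These ESTs were among the brighter ones, with a median signal at percentile 68.6 of all tested probes in the F1 controls. At 10 mg/L, 231 of the 833 probes were not well above background on either array, so their fitted sizes are no measured folds. IGU001_0003_D10.f fell by 8.27 (SE 1.84, adjusted p = 0.00308), from 3.81 ± 0.28 (SD, n = 2) to -4.45 ± 4.02 (n = 2). WTH001_0007_B10.f fell by 8.46 (SE 1.85, adjusted p = 0.00273). Both were well above background on 1 of the 2 exposed arrays, so the sizes rest on a value near the floor. Among the probes measured in both groups, the largest rises were those of IGU001_0004_B08.f, by 4.51 (SE 0.79, adjusted p = 0.000786), and IGU001_0005_F08.f, by 4.31 (SE 0.62, adjusted p = 0.000222), the latter from -2.56 ± 1.23 to 1.75 ± 0.02 (n = 2 each). Against the F2 and F3 controls, which shared the slide of the 10 mg/L arrays, these rises did not pass the test, with log2 differences of 0.57 and 0.78, whereas both named falls did, with -7.73 and -7.80.

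The probes called at 10 mg/L numbered 10157, of which 7269 rose and 2888 fell. Rises were more frequent and smaller: 2371 rises and 2492 falls were at least 2-fold. The probes that rose at least 2-fold were dim in the controls (median percentile 27.8). The median of all tested probes was itself shifted by 0.22. Rises made up 71.6% of the calls in the main scaling, 69.8% with median centring, 69.3% with quantile normalization, 69.6% after normexp, 70.9% with the authors' values and 43.0% of 3826 calls with spike-in centring. The 10 mg/L arrays lay on another slide than the F1 controls. Against the F2 and F3 control arrays of their own slide 10122 probes were called, and of the 10157 probes 6680 were called again in the same direction and 457 in the opposite one. Among the latter were 188 of the rises and 269 of the falls. Without exposed replicate 1 the count was 6253.

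**Figure D2:**
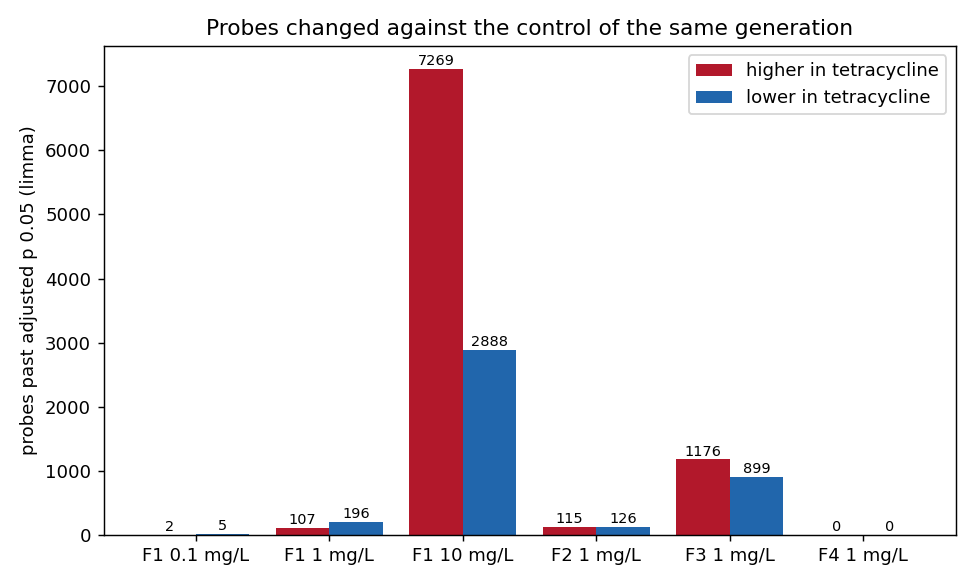
Number of probes past adjusted p 0.05 by limma, higher (red) or lower (blue) than the control of the same generation, for each of the 6 exposures (2 arrays per group, 3 in the 1 mg/L groups of F3 and F4). The bars reach 7269 rises and 2888 falls at 10 mg/L and are at 0 in F4.

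Between doses in F1, the ESTs named for their falls at 1 mg/L lay near the level of the F1 controls at 10 mg/L. They lay below the F2 and F3 controls of the 10 mg/L slide. WTH001_0011_L05.f lay at -3.16 in the controls, -4.48 at 0.1 mg/L, -6.18 at 1 mg/L and -3.48 at 10 mg/L, and IGU001_0028_H08.f at -1.16, -2.53, -4.10 and -1.46. The means of these 2 ESTs ran nearly parallel, and whether both come from 1 transcript was not tested. They were chosen for low values at 1 mg/L, so a return towards the control level is partly built in. The F1 controls also lay on another slide than the 10 mg/L arrays. On the 10 mg/L slide, WTH001_0011_L05.f lay at -1.66 in the F2 and -1.85 in the F3 controls. IGU001_0028_H08.f lay there at 0.065 and 0.043. A return to the control level therefore cannot be told apart from a slide difference. Of the 196 probes that fell at 1 mg/L, 132 were called lower and 33 higher at 10 mg/L than the F1 controls, by which they were chosen. Against the F2 and F3 controls of the 10 mg/L slide, 53 of them were called lower and 75 higher. The F-test over the 3 doses called 9874 probes, the smallest adjusted p being 2.91e-07. Among the brightest probe of each EST, measured in every group, WTH001_0014_I14.f and IGU001_0055_G02.f had the smallest p (both with adjusted p = 6.21e-06). WTH001_0014_I14.f lay at 0.30, 0.66, 0.48 and 2.73 from 0 to 10 mg/L. Without 10 mg/L replicate 1 this test called 4511.

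Set directly against 1 mg/L, 10 mg/L gave 8222 called probes, 4937 higher and 3285 lower. WTH001_0001_N16.f, well above background on 1 of the 2 arrays at 1 mg/L, was higher by 3.98 (SE 0.51, adjusted p = 8.81e-05) and WTH001_0003_M13.f by 3.93 (SE 1.19, adjusted p = 0.0232). WTH001_0007_B10.f and IGU001_0003_D10.f were lower, by log2 differences of -7.64 (SE 1.85, adjusted p = 0.00711) and -7.53 (SE 1.84, adjusted p = 0.00757). These 2 groups also lay on different slides. The count was 3508 without 10 mg/L replicate 1 and 3293 without 1 mg/L replicate 2. Between 1 and 0.1 mg/L limma called 0 probes. Among the brightest probe of each EST, the smallest p values belonged to WTH001_0014_N20.f, at -6.88 ± 0.06 with 0.1 mg/L and not well above background with 1 mg/L, and to IGU001_0056_B05.f, at -0.47 ± 0.34 and -2.13 ± 0.15 (n = 2 each), both with adjusted p = 0.0514. At an unadjusted p under 0.05 there were 3788 probes. Other settings called up to 1227 probes here, among them 274 with median centring and 270 with quantile normalization, of which 266 and 258 were lower at 1 mg/L. Without 1 mg/L replicate 1 the count was 110, and it was 1 without 0.1 mg/L replicate 1.

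Across all probes, log2 differences correlated at 0.577 between 0.1 and 1 mg/L, 0.303 between 0.1 and 10 mg/L and 0.236 between 1 and 10 mg/L. Probes are not independent replicates, and all 3 comparisons use the same 2 controls. Simulated unchanged groups against shared controls gave a correlation of 0.502 and a covariance of 0.093, beside observed covariances of 0.150, 0.168 and 0.179. The simulation used the spread pooled over all groups, so its values are not those of the F1 controls' own spread. The residual SD was 0.329 in the F1 controls and ranged from 0.277 to 0.617 between groups. Both 1 and 10 mg/L called 93 probes higher, where independent lists would share 26.9, and 132 lower, where they would share 19.6, and 37 were called in opposite directions. With 1 control array for each dose, so that no array was shared, the correlations were 0.352 and 0.255 for 0.1 and 1 mg/L, 0.174 and 0.182 for 0.1 and 10 mg/L, and 0.129 and 0.174 for 1 and 10 mg/L. The overlap of 1 and 10 mg/L was then 29 higher (7.02 for independent lists), 33 lower (7.96) and 16 opposite one way, and 4 higher (1.67), 10 lower (6.06) and 12 opposite the other way. In all these overlaps the F1 controls lay on another slide than the 10 mg/L arrays. Against controls of the 10 mg/L slide (F2 and F3), 12 rises at 1 mg/L were called higher and 7 lower. Of the 196 falls, 53 were called lower and 75 higher. There 84.1% of the rises lay above 0 (61.6% of all probes) and 56.1% of the falls below 0 (38.4%). The overlap of calls therefore cannot be told apart from a slide difference, and those controls also differ in generation.

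**Figure D3:**
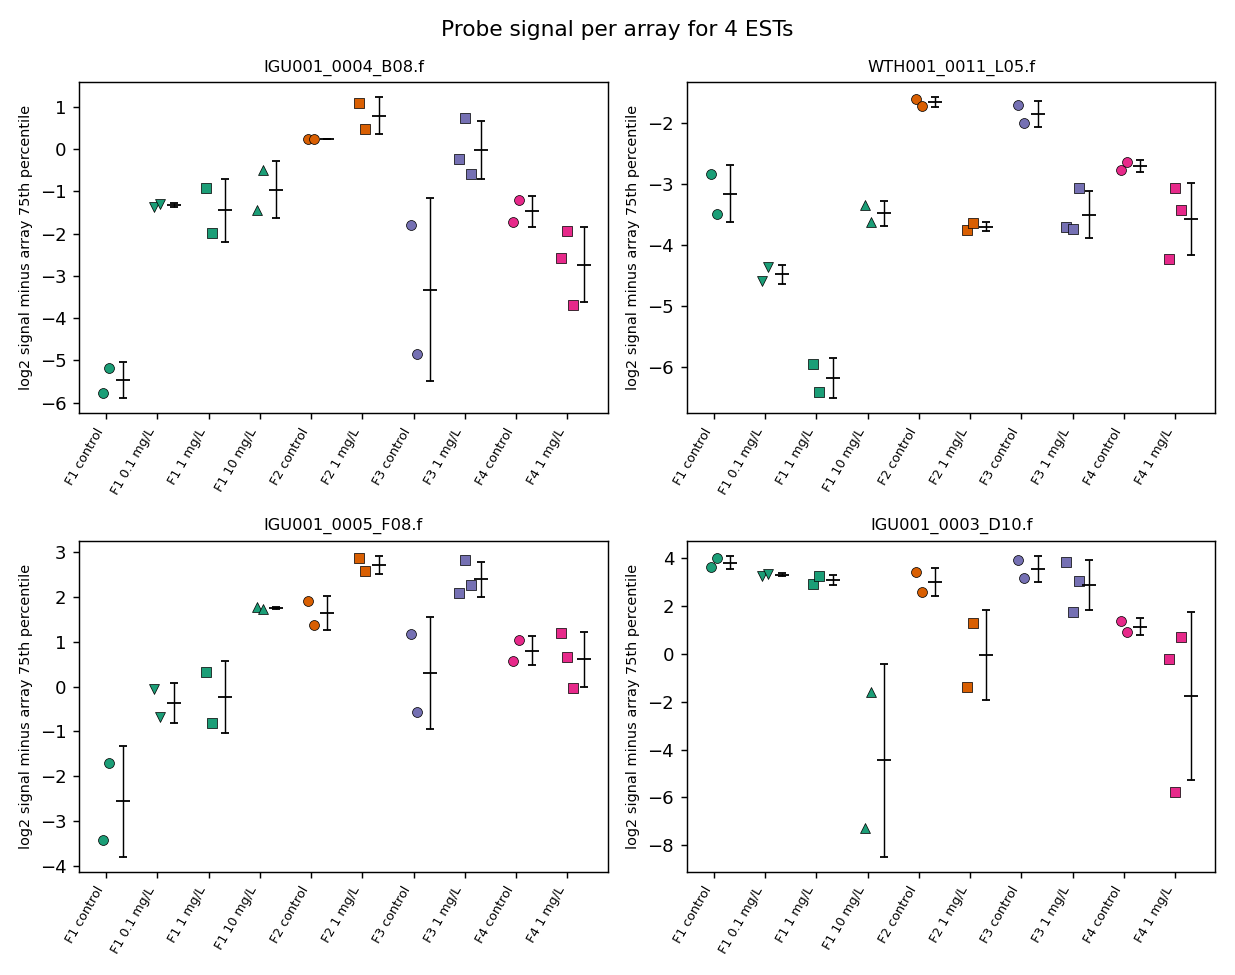
Normalized log2 signal (log2 signal minus the array's 75th percentile) of the brightest probe of 4 ESTs on each array, with the mean and SD of each group beside the points (n = 2, or 3 in the 1 mg/L groups of F3 and F4). WTH001_0011_L05.f is lowest at 1 mg/L in F1, with a mean of -6.18, and IGU001_0003_D10.f spreads widely at 10 mg/L in F1, with an SD of 4.02.

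In F2, ESTs lower at 1 mg/L than in the controls moved by more than those that were higher. WTH001_0009_I17.r fell by 2.99 (SE 0.59, adjusted p = 0.0352) and WTH001_0004_D18.f by 2.77 (SE 0.32, adjusted p = 0.00638), from -2.68 ± 0.28 to -5.45 ± 0.03 (SD, n = 2 each), where it was well above background on 1 of the 2 arrays. IGU001_0018_H05.f rose by 1.48 (SE 0.30, adjusted p = 0.036) and IGU001_0029_B05.f by 1.36 (SE 0.29, adjusted p = 0.0499). Of 241 called probes, 115 were higher and 126 lower, and 45 and 120 of them changed at least 2-fold. The 833 probes that had fallen at least 8-fold at 10 mg/L in F1 had a median log2 difference of -1.38 here, and 95.4% of them lay below 0, while the median of all probes was 0.19. Only 7 of the 833 were called. The share of higher calls was 47.7%, against 62.2% with quantile normalization, 74.6% after normexp, 75.9% with the authors' values and 0 of 9 calls with spike-in centring. The count was 130 or 2 without control replicate 1 or 2, 109 without exposed replicate 1, and 0 by limma when only these 4 arrays were fitted (6629 at an unadjusted p under 0.05).

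In F3, falls of ESTs that were near background at 1 mg/L stood beside rises. WTH001_0014_I07.r fell by 4.83 (SE 0.99, adjusted p = 0.0167) and WTH001_0001_I20.f by 4.01 (SE 0.88, adjusted p = 0.0205), and each was well above background on 1 of the 3 exposed arrays. IGU001_0004_B08.f, among the largest rises at 1 and 10 mg/L in F1, rose by 3.30 (SE 0.72, adjusted p = 0.0208), with control values of -3.32 ± 2.17 (SD, n = 2). WTH001_0003_E02.f, well above background on 1 of the 2 control arrays, went from -6.25 ± 2.53 (SD, n = 2) to -3.15 ± 0.64 (n = 3), with adjusted p = 0.0414, for 1 of its 3 probes. Of 2075 called probes, 1176 were higher and 899 lower, and 340 ESTs had at least 2 probes higher and 277 at least 2 lower. Spike-in centring shifted the median of all probes from 0.05 to 0.60 and gave 986 higher and 87 lower calls. The exposed arrays lay on another slide than the F3 controls, and against the F4 controls of their own slide 6600 probes were called. Of these, 1060 were among the 2075, counted without regard to direction, so they are no count of changes found again. None of the 4 named probes passed there: the log2 differences were -0.92 and -0.77 for the falls of WTH001_0014_I07.r and WTH001_0001_I20.f, 1.44 for IGU001_0004_B08.f and 0.94 for WTH001_0003_E02.f. The count was 818 or 124 without control replicate 1 or 2, 419 or 4219 without exposed replicate 2 or 3, and 0 by limma when only these 5 arrays were fitted (3810 at an unadjusted p under 0.05).

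In F4, limma called 0 probes at 1 mg/L, with 1657 at an unadjusted p under 0.05 where chance gives 1444. Among the brightest probe of each EST, the smallest p values belonged to WTH001_0011_H19.f, at -7.04 ± 0.03 (SD, n = 2) in controls and -7.89 ± 0.22 (n = 3) at 1 mg/L, and to WTH001_0006_O20.r, at -8.75 ± 0.20 and -6.92 ± 0.21, both with adjusted p = 0.431. WTH001_0011_H19.f was not well above background on any F4 array, and WTH001_0006_O20.r on 1 exposed and 0 control arrays. The 833 probes of the 8-fold set had a median log2 difference of -1.70, with 92.2% below 0 and 0 called. On the F4 1 mg/L arrays the median signal of this set was -3.60, -6.64 and -2.76, against -2.81 and -2.90 on the F4 controls. The count was 85 without exposed replicate 2 (9 higher and 76 lower), 112 or 0 without control replicate 1 or 2, and 2 or 4 without exposed replicate 1 or 3. On simulated data of this comparison, the same fit recovered 46% of 2-fold and 79% of 4-fold changes. The simulation gave all groups the same spread, whereas the F4 1 mg/L group had the largest residual SD of all groups (0.617). It therefore does not give the recovery at the spread of that group, which may be lower.

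**Figure D4:**
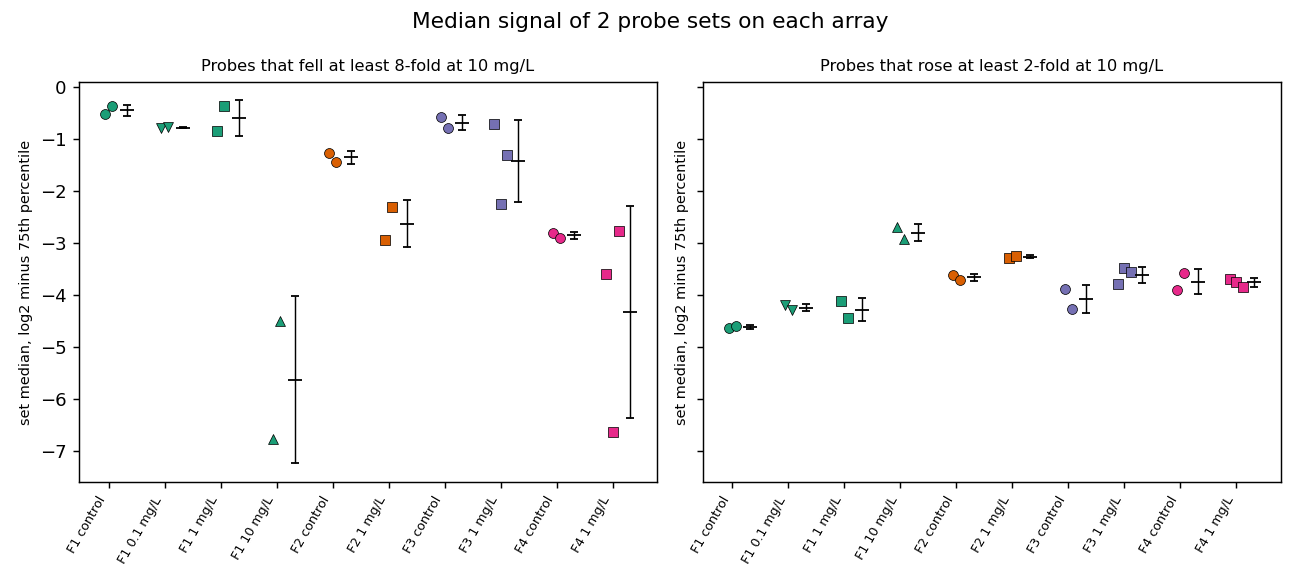
Median normalized log2 signal, on each array, of the 833 probes that fell at least 8-fold and the 2371 that rose at least 2-fold at 10 mg/L in F1, with the mean and SD of each group beside the points. The 8-fold set is at -6.77 and -4.50 on the 10 mg/L arrays that define it, and at -6.64 on 1 of the 3 F4 1 mg/L arrays.

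Averaged over the 4 generations, 1 mg/L raised 3191 probes and lowered 1341, of 4532 called. Among the probes measured in both groups and with no overlap in any generation, IGU001_0022_G10.f fell by 3.35 (SE 0.80, adjusted p = 0.019) and WTH001_0010_F09.f fell by 2.51 (SE 0.63, adjusted p = 0.0222). The former was well above background on 1 exposed array each in F2 and F4. At 1 mg/L it spread widely between replicates, with an SD of 4.85 in F2 (n = 2) and 2.12 in F4 (n = 3). For WTH001_0010_F09.f these SDs were 2.985 and 2.60. The averaged falls of both therefore rest on uneven replicates. IGU001_0045_D01.f rose by 0.72 (SE 0.12, adjusted p = 0.00301) and WTH001_0007_O11.f by 0.67 (SE 0.14, adjusted p = 0.0109). Exposed and control arrays did not overlap in any of the 4 generations for 286 probes that were higher and 115 that were lower. If arrays were exchangeable within each generation, chance would give 1 in 3600, or about 8 probes, each way. The 2 F3 groups lay on different slides, so they are not exchangeable, and a slide difference could add to these counts. Probes are not independent either, so a chance count can lie far from 8. Most rises were small: 235 rises and 719 falls were at least 2-fold. The share of higher calls was 70.4%, against 44.3% of 920 calls with spike-in centring. Over the 3 generations whose arrays shared a slide, leaving out F3, the count was 550 (289 higher and 261 lower), WTH001_0010_F09.f and WTH001_0007_O11.f no longer passed, and it was 777 without F2 and 2914 without F1. Leaving out 1 array lowered it by over 1.5 times for F1 control replicates 1 and 2 (1580 and 2918), F1 1 mg/L replicate 1 (1848), F2 control replicate 2 (1315), F2 1 mg/L replicate 1 (2118), F3 control replicate 2 (2258), F4 control replicates 1 and 2 (1730 and 2758) and F4 1 mg/L replicate 1 (2955).

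The 1 mg/L effect differed between generations at 97 probes from 60 ESTs by the F-test of the interaction. The smallest adjusted p was 0.0167. Among the brightest probe of each EST, measured in every group, IGU001_0014_H02.f and IGU001_0027_E01.f had the smallest p, both with adjusted p = 0.0179. IGU001_0014_H02.f went from 0.56 to -1.43 in F1 and from 0.48 to -0.86 in F3, but from -1.49 to -0.09 in F2 and from -0.56 to -0.19 in F4. Between pairs of generations, 59 probes differed between F2 and F1, 45 between F3 and F2, 29 between F4 and F3, 4 between F4 and F1 and 1 between F4 and F2. Between F3 and F1 limma called 0, with 3062 at an unadjusted p under 0.05. The interaction count was 10 without F1 1 mg/L replicate 2, 0 or 1 without F2 control replicate 1 or 2, 154 without F2 1 mg/L replicate 2, 160 without F3 control replicate 1, 177 or 170 without F3 1 mg/L replicate 2 or 3 and 202 or 17 without F4 control replicate 1 or 2. Spike-in centring gave 0 by limma (3208 at an unadjusted p under 0.05), and the 3 generations with both groups on 1 slide gave 58.

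Effects of 1 mg/L were positively correlated among F1, F2 and F3, and near 0 between F4 and F1 or F3. Across probes, the log2 differences correlated at 0.524 between F1 and F3, 0.556 between F2 and F3 and 0.392 between F1 and F2, with no array shared. F4 correlated at -0.029 with F1, -0.010 with F3 and 0.266 with F2. Without F2 1 mg/L replicate 1 the value for F1 and F2 was 0.227, and without F4 control replicate 1 that for F2 and F4 was 0.114, so the order of these pairs is not settled. F1 and F3 shared 68 probes called higher, where independent lists would share 4.36, and 78 called lower, where they would share 6.10, and 0 were called in opposite directions. F2 and F3 shared 48 higher and 70 lower, where 4.68 and 3.92 would be shared, and 7 were called in opposite directions. F1 and F2 shared 1 higher and 26 lower, where 0.43 and 0.86 would be shared, and 3 were opposite. The F1 10 mg/L effect correlated with the 1 mg/L effect at 0.423 in F2, 0.237 in F3 and 0.457 in F4, with no array shared. The values for F2 and F4 lay above the 0.392 between F1 and F2 at 1 mg/L. A correlation of that size is therefore not particular to the 1 mg/L effects.

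Control animals also differed between generations. WTH001_0014_E06.f lay at 1.76 ± 0.01 in F1, 0.19 ± 0.01 in F2, -0.68 ± 0.01 in F3 and 3.08 ± 0.14 in F4 (SD, n = 2 each), and IGU001_0039_A12.f at 1.16 ± 0.06, -0.92 ± 0.30, -1.91 ± 0.40 and 2.09 ± 0.22, both with adjusted p = 1.92e-06 by the F-test, the smallest p among the brightest probe of each EST measured in every group. That test called 7457 probes among the 4 control groups, the smallest adjusted p being 1.01e-07. The F2 and F3 controls, which shared a slide, differed at 653 probes, while F2 differed from F1 at 4295 and F4 from F3 at 4521, across slides. Slide and generation cannot be told apart in the latter.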

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

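Both tests of slide and that of a single array at 10 mg/L, all tests on the first component, and that of a single array in F4 were chosen only after the result was seen.

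The effect of 1 mg/L differed between generations at 97 probes by the interaction test. The pairwise tests gave 59 probes between F2 and F1, 45 between F3 and F2, 29 between F4 and F3, 4 between F4 and F1 and 1 between F4 and F2. Spike-in centring gave 0 by limma (3208 at an unadjusted p under 0.05), and the generations with both groups on 1 slide gave 58. IGU001_0014_H02.f and IGU001_0027_E01.f had adjusted p = 0.0179 each by limma, with the effect in F1 and F3 opposite in direction to that in F2. Their means ran nearly parallel: 0.56 and -0.88 in F1 controls, -1.43 and -2.73 at 1 mg/L in F1, and -1.49 and -2.72 in F2 controls. Whether both come from 1 transcript was not tested, so they may not count as 2 separate cases.

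The count for the mean over generations was set against other splits. Of 100 splits that shuffled exposed and control arrays within generations, drawn from 3600 and with the real one included, 1 gave as many probes as the real 4532, and the highest of the others gave 988. Chance differences between single arrays were thereby argued against for this count. The labels do not say whether replicates came from separate aquaria. If they did not, a chance difference between aquaria would follow the real labels, and shuffling arrays cannot exclude it. Slide stays open for the F3 share of the count and, through the shared spread, for the test as a whole.

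The size of the 10 mg/L response in F1 could come from the slide, from 1 array or from the centring. As the whole cause of the number of probes the slide was argued against: within it, the 10 mg/L arrays differed at 10507 probes from the F2 and at 8490 from the F3 controls, which differed from each other at 653, and dose and generation stay open. For the direction of single probes, taken over all those called, slide and dose cannot be told apart. Probes were called with 1 of the 10 mg/L arrays against the F1 controls, and the other was set against F2 or F3 controls of its slide. Between 67.4% and 90.6% kept their sign (84.5% to 95.4% of rises, 38.9% to 80.9% of falls). The F2 and F3 controls, which met no dose, gave 64.6% to 79.8% and 46.1% to 68.2% in the same test. For the 833 probes that fell at least 8-fold, slide was argued against as the whole cause. Against the F2 and F3 controls of that slide their median log2 difference was -4.32, and 831 were called lower. They were chosen on the same 10 mg/L arrays, which favours values below 0, and generation stays open. Without either array the lower count was 6253, which speaks against 1 deviating array. By these scalings the surplus of rises cannot be told apart from a shift of the whole array. Subtracting the median of 0.22 lowered their share from 71.6% to 53.4%, in part by construction. Other scalings gave 69.3% to 70.9%, and spike-in centring gave 43.0%. The 75th percentile minus the spike-ins averaged -0.22 in the F1 controls and -0.26 at 10 mg/L. Spike-in centring therefore moved these groups little against each other, and its lower share does not measure such a shift.

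The 10 mg/L arrays and the F4 arrays lay on the same side of the first component. The lowest F4 array lay 95.7 above the highest F3 1 mg/L array of the same slide, so slide alone did not set the position. That gap was read off the same scores as the pattern, so it is no separate test of slide. Signal strength was argued against. Over the 22 arrays the log2 75th percentile correlated with the component at r = 0.112 (permutation p = 0.617) and Spearman's rho = -0.008 (permutation p = 0.971). Without the 2 arrays farthest from the median r was 0.158. Whether the groups share a change of expression cannot be told apart from separate changes: the 10 mg/L effect correlated with the difference between F4 and F3 controls, which shares no array with it, at 0.324 across probes, and with that between F4 and F2 controls at 0.182. Generation, age of the cultures and slide differ together in these differences.

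The F4 effect of 1 mg/L did not follow those of F1 and F3 at 1 mg/L. With the F1 10 mg/L effect it correlated at 0.457, with no array shared, and how far that rests on 1 array was not tested. A single array was argued against as the reason for the low values with F1 and F3. Without F4 1 mg/L replicate 2 the correlation was -0.084 with F1 and 0.008 with F3. Noise between arrays cannot be told apart from a true difference: effects from non-overlapping F4 arrays correlated at between -0.055 and 0.329, and at between 0.54 and 0.581 in F1, 0.48 and 0.622 in F2 and 0.317 and 0.538 in F3. No biological explanation beyond generation was tested.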

How the results depend on the processing

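Signals near background limit the falls named at 10 mg/L and in F3, and 2 or 3 arrays per group limit every count. No named probe changed direction under other settings: of 407 values, 340 kept their side of the threshold, 49 lost it and 18 gained it. None of 178 values with 1 array left out changed direction either. For most named probes that was fixed in advance, since they were chosen for no overlap between the groups' arrays. Against the controls of its own slide the 10 mg/L count in F1 was 10122, with 457 of the 10157 probes called in the opposite direction. Without a filter every count stayed within 1.5 times. Where a count moved, the cause was not tested, except where fewer units or samples were used. Alternatives chosen after seeing the data were spike-in centring, the mean over the probes of an EST, leaving out 2 arrays, crossed numbers and 1 control array for each dose. The gene list tests were not run because no list could be applied. Slide as a block was not run, since every group lay on 1 slide and the cross-slide comparisons are then not estimable.

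Median centring gave 456 for F1 1 mg/L and 274 for 1 against 0.1 mg/L. Quantile normalization gave 532 for F2 and 270 for 1 against 0.1 mg/L. Normexp gave 17 for 0.1 mg/L, 587 for F1 1 mg/L, 1265 for F2, 3338 for F3 and 420 for 1 against 0.1 mg/L. The authors' values, over 10318 ESTs, gave 3 for 0.1 mg/L, 3577 for 10 mg/L, 485 for F2, 1369 for F3, 1882 for the mean, 39 for the interaction, 3682 for the dose test, 167 for 1 against 0.1 mg/L, 3479 for 10 against 1 mg/L and 3080 for the controls. Probes well above background on all arrays gave 2 for 0.1 mg/L, 504 for F2 and 203 for 1 against 0.1 mg/L. Trend and robust settings gave 3, 527 and 241 for the same results.

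Array quality weights gave 176 for 0.1 mg/L, 1231 for F1 1 mg/L, 3509 for F2, which is above the 2388 for F3, 8627 for the mean, 474 for the interaction, 1227 for 1 against 0.1 mg/L and 12896 for the controls. A 2-fold minimum gave 4863 for 10 mg/L, 1270 for F3, 954 for the mean, 4872 for the dose test and 4275 for 10 against 1 mg/L. Only the groups compared, with 2 residual degrees of freedom in pairs of 2, gave 0 for 0.1 mg/L, F2 and F3, 931 for F1 1 mg/L, 4838 for 10 mg/L and 3831 for 10 against 1 mg/L. Against the F4 controls of the same slide F3 gave 6600. Generations with both groups on 1 slide gave 550 for the mean and 58 for the interaction. The mean was 2914, 777 and 550 without F1, F2 and F3.

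The mean over the probes of an EST gave 138 for F1 1 mg/L, 3810 for 10 mg/L, 853 for F3, 1861 for the mean, 35 for the interaction, 3739 for the dose test, 80 for 1 against 0.1 mg/L, 3065 for 10 against 1 mg/L and 2854 for the controls. Spike-in centring gave 1 for 0.1 mg/L, 3826 for 10 mg/L, 9 for F2, 1073 for F3, 920 for the mean, 0 for the interaction, 3657 for the dose test, 273 for 1 against 0.1 mg/L, 3375 for 10 against 1 mg/L and 3755 for the controls. It shifted the median of all probes to -0.08 in F1 1 mg/L, -0.10 in F2 and 0.60 in F3. Without F1 10 mg/L replicate 1 and F4 1 mg/L replicate 2, counts were 71 for F4, 6938 for the mean, 5648 for the dose test and 4522 for 10 against 1 mg/L.

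With the replicate number as a block, F2 gave 111, the interaction 32 and 1 against 0.1 mg/L 240, and no other count moved by over 1.5 times. The numbers did not pair the samples: deviations of same-numbered arrays correlated at between -0.196 and 0.04. In F2 the value was -0.176, and the crossed pairing gave 40 higher and 83 lower calls, against 115 and 126.

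Leaving out 1 array, where a lone sample is assumed to vary like the other groups, gave 0 to 83 for 0.1 mg/L, 41 to 148 for F1 1 mg/L, 6253 to 11633 for 10 mg/L, 2 to 299 for F2, 124 to 4219 for F3, 0 to 112 for F4, 1315 to 5730 for the mean, 0 to 202 for the interaction, 4511 to 11011 for the dose test, 0 to 110 for 1 against 0.1 mg/L, 3293 to 10037 for 10 against 1 mg/L and 5491 to 6718 for the controls. Correlations of effects ranged from 0.227 to 0.465 for F1 and F2, 0.404 to 0.577 for F1 and F3, -0.084 to 0.059 for F1 and F4, 0.371 to 0.617 for F2 and F3, 0.114 to 0.379 for F2 and F4 and -0.112 to 0.103 for F3 and F4. With 1 control array for each dose they were 0.352 and 0.255 for 0.1 and 1 mg/L and 0.174 and 0.182 for 0.1 and 10 mg/L. Between doses they ranged from 0.473 to 0.668 for 0.1 and 1 mg/L, 0.244 to 0.349 for 0.1 and 10 mg/L and 0.132 to 0.303 for 1 and 10 mg/L.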

Other observations

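The tests of the set described here, with its random and its spread-matched lists, were chosen only after its median on each array was seen. The 833 probes (297 ESTs) that fell at least 8-fold at 10 mg/L also varied in groups that never met that dose. Their median signal was -0.52 and -0.37 on the F1 controls and -0.57 and -0.79 on the F3 controls, but -2.81 and -2.90 on the F4 controls and -6.64 on 1 of 3 F4 1 mg/L arrays. In F3 at 1 mg/L the 3 arrays lay at -0.70, -2.26 and -1.31. The difference between F4 and F3 controls had a median of -1.75 in this set, with 99.9% of the probes below 0 and 225 called lower, while the median of all probes was -0.12.

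At 1 mg/L its median log2 difference from the controls was -1.38 in F2 (95.4% of the probes below 0, 7 called lower), -0.70 in F3 (91.2%, 25 called) and -1.70 in F4 (92.2%, 0 called by limma). The F3 value is across slides, and the F3 1 mg/L arrays lay above the F4 controls of their own slide. The F4 value rests on replicate 2: the set's medians on the other F4 1 mg/L arrays were -3.60 and -2.76, the latter above both controls. In F1 the values were -0.38 at 0.1 mg/L and -0.26 at 1 mg/L, against the same 2 control arrays by which the set was chosen, which favours values below 0. One hypothesis is that these ESTs form a set that rises and falls together between pools of animals of the same group. Over the 18 arrays of the 8 other groups, deviations from the group means correlated between each member and the mean of the other members at a median of 0.915, against at most 0.326 over 1000 random lists matched on brightness. Without F4 1 mg/L replicate 2 the value was 0.87 against at most 0.362. Lists of 779 probes matched on spread between replicates gave at most 0.232, and the probes that rose at least 2-fold at 10 mg/L gave 0.451. These values are consistent with such a set. Whether several of these ESTs come from 1 transcript was not tested, and that could raise their correlation above that of random lists. What such a set would follow was not tested, and the ESTs carry no gene names here.

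The array's probes differed in signal by clone series and read end, which does not measure transcript levels, since probes differ in affinity. Probes of .r reads of the IGU and WTH series had median normalized signals of -5.05 and -4.84, against -0.85 and -2.61 for .f reads. At 10 mg/L, the .r reads gave 27.3% and 28.65% higher calls and 8.70% and 8.52% lower calls, and the .f reads gave 26.6% and 22.2% higher and 9.60% and 11.1% lower.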
